A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

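Total RNA of 6 samples of Saccharomyces cerevisiae was measured on a yeast expression array, 3 wild-type arrays, 2 rrp6 arrays and 1 double-mutant array. The values were deposited as linear probe set intensity without a stated method. The deposited intensity of wild type 3 and the double mutant never fell below 0 and had a mean near 99.5 and 99.7 after trimming 2% at each end. The other 4 arrays held negative values, 440 and 380 for wild types 1 and 2 and 367 and 369 for rrp6, and had trimmed means of 1000, 999.5, 1000 and 1000. The software behind the deposited values and the genome build of the array are not given in the sources used here, so no coordinates are printed.

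The design, the gene lists, the tests of the comparisons and the alternatives were fixed before the data were examined, with some exceptions. These were 2 alternatives with a floor per array set, a scaling to spiked controls, and the 2-fold limits for classes and overlap. The tests named in the closing section as chosen later were further exceptions. The rule set beforehand was to use the values as deposited if trimmed means agreed within 5%. Otherwise all 6 arrays were to be quantile normalized, which applied. Values under the 20th percentile of all pooled values (42.3, or 5.40 on the log2 scale) were set to that floor and log2 was taken. Of 9275 probe sets that are not controls, the 7882 above the floor on at least 2 arrays were tested. A difference against a group at the floor on all of its arrays is a bound. Current gene names were taken from a reference annotation. It gave 6504 probe sets exactly 1 gene (5656 genes), 328 several genes and 2443 none. No gene is named from a probe set of several genes.

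Correlations between arrays were 0.975 for wild types 1 and 2, 0.971 for the rrp6 pair, 0.926 for wild type 3 and the double mutant, and 0.886 and 0.897 for wild type 3 and wild types 1 and 2. The median absolute log2 difference between replicates was 0.27 for the wild-type pair and 0.26 for the rrp6 pair.

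One limma model (limma 3.58.1, R 4.3.3; eBayes with a variance trend) held 4 cell means, those of wild types 1 and 2, wild type 3, rrp6, and the double mutant. It left 2 residual degrees of freedom and had 1.54 prior degrees of freedom. The spread comes from 1 array set only. Contrasts were rrp6 against wild types 1 and 2, the double mutant against wild type 3, the difference of both, and wild type 3 against wild types 1 and 2. Tests were two-sided with Benjamini-Hochberg adjustment over the probe sets tested, and a call is an adjusted p under 0.05. Of the tested probe sets, 124 had no spread at all because they lay at the floor on the replicated arrays.

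Gene lists, 29 in number, were tested with camera at a preset correlation of 0.01 over 5445 genes, each by its brightest probe set, adjusted over the lists of a contrast. Each was repeated with a correlation estimated per list, where camera tests on the 2 residual degrees of freedom of the fit. Classes of probe sets were compared by Fisher's exact test.

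Named genes were, for each mutant, the 10 highest and 10 lowest called probe sets with 1 gene and the same direction on every array pair. For the difference between mutants they were the 5 highest and 5 lowest, as values where none was called. RRP6, PAP2, HIS3, TRP1 and all mating-type list members were always named, with up to 4 called members of each list, or its 2 largest differences as values where none was called. Others are said to be chosen after their values were seen.

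The fit was tested on simulated data, with variances drawn from the fitted prior and 200 of 7882 probe sets changed in each of 20 runs. For rrp6 it recovered 2% of 2-fold, 43.9% of 4-fold, 66.6% of 8-fold and 79.7% of 16-fold changes, with 4.09% false calls. For the double mutant the shares were 0.1%, 4.5%, 28.5% and 48.8%, with 3.65% false calls. Camera found a shifted list of 20 members in 20 of 20 runs and passed 0 of 200 unchanged lists. These data follow the assumptions of the fit, among them that wild type 3 and the double mutant vary like the replicated arrays. Unlike the real values, the simulated ones were not cut off at the floor. The simulation therefore cannot show the share of changes recovered or of false calls on the real arrays. Estimated correlations of real lists were, for example, 0.62 for snoRNA and snRNA genes, 0.44 for general stress and 0.0091 for amino acid synthesis. How camera fares at those above the preset 0.01 is not settled by the simulation.

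Alternatives were other scalings, floors, filters, thresholds and variance models, other groupings of the controls, a replicate block, each replicate left out, and genes in place of probe sets. Control probe sets took no part in the tests, apart from that scaling. No group had enough arrays for a test of single arrays against their group or of other splits of the samples. Per-sample columns not used numbered 0.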

Results

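Transcript signal was measured from total RNA of budding yeast with a yeast expression array of 9335 probe sets, 60 of them controls. The strains were the wild type (BMA64), a strain lacking RRP6, the nuclear exonuclease of the RNA exosome, and a strain lacking both RRP6 and TRF4. TRF4, listed under its standard name PAP2, encodes the poly(A) polymerase of the TRAMP complex. There were 3 wild-type arrays, 2 rrp6 arrays and 1 double-mutant array. All strains grew in rich medium at 30 °C, to an optical density of 0.6, or below 0.6 for the double mutant. Wild-type array 3 was labelled as the control of the double mutant, so wild-type arrays 1 and 2 served as the controls of rrp6. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so limma's p-values measure only the spread between these samples. For the double mutant that spread is borrowed from the pairs of wild types 1 and 2 and of rrp6. Fisher and permutation p-values, and those of camera at the preset correlation, rest on genes or probe sets, not on separate cultures.

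The deleted genes read as absent in the strains that lack them. RRP6 (8562_at) had deposited intensities of 936.3 and 1233.1 in wild types 1 and 2, 75.3 in wild type 3, −22.9 and −47.9 in the rrp6 arrays, and 0.7 in the double mutant. PAP2 (8673_at) had 136.4, 173.1 and 18.6 in wild types 1 to 3, 170.3 and 209.9 in the rrp6 arrays, and 0.5 in the double mutant. The deposited scale of wild type 3 and the double mutant differs from that of the other arrays. After normalization, RRP6 fell by at least 18.3-fold in rrp6 (adjusted p = 0.048, lower in 2 of 2 arrays). In the double mutant RRP6 lay at least 16.7-fold below wild type 3 (adjusted p = 0.083) and PAP2 at least 4.49-fold below it (adjusted p = 0.107). HIS3, which replaced RRP6 in rrp6 according to the labels, differed by −0.10 and 0.00 (log2) at its 2 probe sets in rrp6, and by −0.79 and −0.75 in the double mutant, with adjusted p of at least 0.395. Against wild types 1 and 2, HIS3 stood at −0.63 and 0.10 in the double mutant. TRP1, an enzyme of tryptophan synthesis, read 4.7, 662.6 and 4 in wild types 1 to 3, 5.8 and 596.9 in the rrp6 arrays, and 38.4 in the double mutant.

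**Figure D1:**
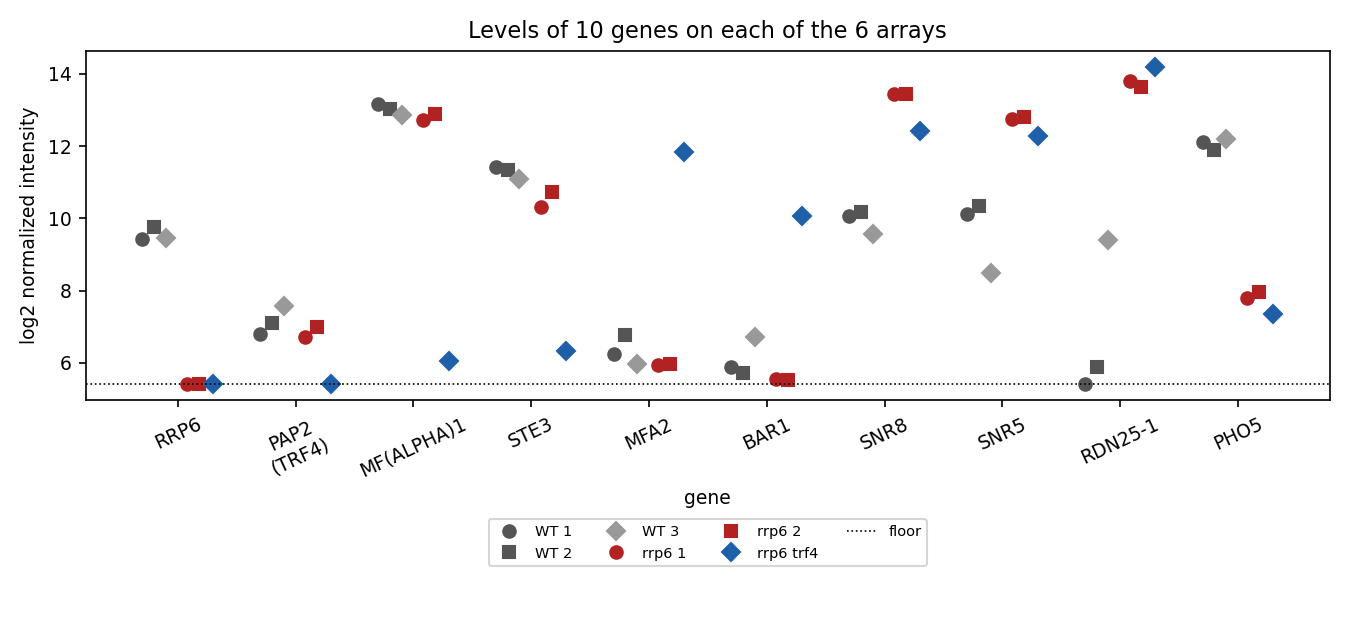
Normalized log2 intensity (vertical axis) of 10 genes on each of the 6 arrays, 1 point per array, with the floor as a dotted line. RRP6 sits at the floor on the 3 mutant arrays and PAP2 on the double-mutant array alone. MF(ALPHA)1 and STE3 are low, and MFA2 and BAR1 high, on that array.

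The first comparison asked what loss of RRP6 changed. Small nucleolar and spliceosomal RNAs, which guide rRNA modification and pre-mRNA splicing, were higher in rrp6 than in wild types 1 and 2, as were several rRNA probe sets. On wild types 1 and 2 the rRNA control probe sets read at most 130.2, against array medians of 293.5 and 301.3. The signal therefore need not follow abundance in total RNA, where rRNA is plentiful. Whether these rises reflect levels or labelling, for example through poly(A) tails, was not tested. All 59 measured genes of the snoRNA and snRNA list had a positive difference, with a median of 3.34 on the log2 scale. The list rose as a group (camera adjusted p = 9.1e-53; adjusted p = 0.601 with an estimated correlation). Of its members 57 were higher when adjusted over the list alone, and 3 when adjusted over all 7882 tested probe sets. SNR8 (8062_at) rose by 3.33 on the log2 scale, from 10.12 ± 0.08 (SD, n = 2) to 13.45 ± 0.01 (SD, n = 2), with adjusted p = 0.0235. SNR5 (8017_at) rose 5.82-fold, from 10.24 ± 0.14 to 12.78 ± 0.04 (adjusted p = 0.0454), and on wild type 3 it differed from wild types 1 and 2 by −1.74 (adjusted p = 0.0308). SNR64 (10407_at) was at the floor on both controls and rose at least 56.1-fold (adjusted p = 0.0401). SNR44 had the smallest difference, 0.04. Across all probe sets, 15 were called in rrp6, 11 higher and 4 lower, each in the same direction on both rrp6 arrays.

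Among probe sets of ribosomal RNA, RDN25-1 (3766_s_at), the 25S rRNA, rose by 8.08 ± 0.21 (SE, log2; adjusted p = 0.0235), close to a bound since wild types 1 and 2 read 5.41 and 5.88, at or near the floor of 5.40. RDN5-1 (3769_s_at), the 5S rRNA, rose by at least 7.96 (adjusted p = 0.0163), and RDN37-1 (3764_s_at), the rRNA precursor, by at least 6.91 (adjusted p = 0.0163). These probe sets match repeated or overlapping sequences, so the RNA species they read is uncertain. Other probe sets of these genes, chosen after their values were seen, were not called. A second RDN25-1 probe set (3765_s_at) stayed at the floor on all of these arrays. Of 6 other RDN37-1 probe sets, 3 had differences of 0.79, 1.10 and 2.15, 2 were above the floor on rrp6 2 alone and 1 stayed at the floor. A second RDN5-1 probe set (3768_i_at) stood at 7.07 as a bound (adjusted p = 0.0818). RDN18-1, the 18S rRNA, was above the floor on rrp6 2 alone. On wild type 3, the called probe sets of RDN25-1, RDN5-1 and RDN37-1 lay 3.75, at least 3.87 and at least 1.43 above wild types 1 and 2, with adjusted p of 0.0246, 0.0162 and 0.0392. The other called probe sets that were higher are paired with no gene. They were 9225_at, 9835_at, 2290_at, 9836_at and 2737_at, named after their values were seen, with differences of 5.55, 5.12, 4.80, 3.75 and, for the last, at least 2.44. The first was at the floor on wild type 1 and just above it, at 5.65, on wild type 2, so its difference is close to a bound.

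Genes of the phosphate regulon fell in rrp6. The list had a median of −0.85 with all 14 measured members negative (camera adjusted p = 5.3e-07; adjusted p = 0.281 with an estimated correlation). Of these, 8 were lower when adjusted over the list alone and 1 over all probe sets. PHO5 (7274_at), a secreted acid phosphatase, fell by 4.13 ± 0.16 (SE, log2) to a level of 7.87 ± 0.13 (SD, n = 2), with adjusted p = 0.0363. SPL2, a regulator of phosphate uptake, stood at −3.83 (adjusted p = 0.0537). SEO1 (11379_at), a putative permease, fell by at least 4.43 (adjusted p = 0.048), but on wild type 3 it also differed from wild types 1 and 2, by −3.39 (adjusted p = 0.0284). The unnamed probe set 3013_at fell to the floor or near it, with a difference of −2.24 (adjusted p = 0.0401), but it was also at the floor on wild type 3, at least 2.29 below wild types 1 and 2 (adjusted p = 0.0168).

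Genes of amino acid synthesis also fell, with a median of −0.60 and 40 of 41 members negative (camera adjusted p = 4.5e-13; adjusted p = 0.281 with an estimated correlation). Of these, 30 were lower and 1 higher when adjusted over the list alone, and none was called over all probe sets. MET16, of sulphate assimilation, stood at −1.92 and ARG3, of arginine synthesis, at −1.89, and CPA1 at 0.85. MET16 also differed on wild type 3 from wild types 1 and 2, by −2.12 (adjusted p = 0.0308). At a common median the list's median was −1.01. On wild type 3 this list was also below wild types 1 and 2, with a median of −0.49 (camera adjusted p = 6.5e-06; adjusted p = 0.572 with an estimated correlation). Mitochondrial ribosomal protein genes fell, with a median of −0.61 and 52 of 54 negative (camera adjusted p = 3.3e-07; adjusted p = 0.281 with an estimated correlation). None of the 54 passed when adjusted over the list alone, and the largest difference was −1.50 for MRPL17. With the values as deposited the list's median was −0.40, and at a common level of spiked controls −0.035.

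The general stress list fell, with a median of −0.49 and 31 of 38 members negative (camera adjusted p = 2.4e-04; adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 10 were lower and 1 higher. GSY1, a glycogen synthase, stood at −2.61 and GPH1, glycogen phosphorylase, at −2.37, while GRE1 stood at 1.47. The same list was lower on wild type 3 than on wild types 1 and 2, with a median of −1.14 (camera adjusted p = 4.3e-11; adjusted p = 0.572 with an estimated correlation). The call for rrp6 was lost with the 3 wild-type arrays as 1 group and without rrp6 2 (median −0.44, camera adjusted p = 0.0899). The median was −0.16 with the 3 wild-type arrays as 1 group, −0.85 at a common median, −0.78 without wild type 2 and −0.83 without rrp6 1.

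Ribosome biogenesis genes rose, with a median of 0.25 and 57 of 75 positive (camera adjusted p = 2.3e-05; adjusted p = 0.731 with an estimated correlation). None passed when adjusted over the list alone. DBP6 and NOG2, both assembly factors of the large subunit, stood at 1.36 and 1.35. NOG2 overlaps a snoRNA gene, and DBP6 lay 1.58 higher on wild type 3 than on wild types 1 and 2. With the 3 wild-type arrays as 1 group, the median of this list turned to −0.10, and without wild type 1 it was 0.10 (camera adjusted p = 0.1002). It was 0.11 without rrp6 2, 0.44 without wild type 2 or rrp6 1, 0.14 at a common median and 0.47 with the values as deposited. Cytosolic ribosomal protein genes passed as lower, with a median of −0.10 and 67 of 80 negative (camera adjusted p = 0.00945, adjusted p = 0.731 with an estimated correlation). All probe sets of protein-coding genes had a median of −0.089, so by median this list hardly fell below other genes in the reported setting. Adjusted over the list alone, 1 was higher and 0 lower, RPS28B at 1.31, which on wild type 3 lay 1.64 above wild types 1 and 2 (adjusted p = 0.0224). Without wild type 2 the camera adjusted p was 0.294. The size depended on the scaling, with medians of −0.71 at a common median, −0.50 at a common 75th percentile and −0.39 with the values as deposited. Iron regulon genes rose, with a median of 0.32 and 15 of 18 positive (camera adjusted p = 0.0249; adjusted p = 0.731 with an estimated correlation), and 1 was lower when adjusted over the list alone. TIS11, an mRNA-binding protein of iron starvation, stood at 1.52 and FIT2, a cell wall mannoprotein, at −1.44, against −2.06 for FIT2 on wild type 3 (adjusted p = 0.0349). At a common median the list's median was 0.094. The PAU, DAN and TIR cell wall genes rose, with a median of 0.53 and 11 of 15 positive (camera adjusted p = 0.0442; adjusted p = 0.731 with an estimated correlation), and 0 passed when adjusted over the list alone. TIR4 stood at 1.75. This call was lost in 10 of 19 other settings, among them the values as deposited, a common median, a common 75th percentile, a lower floor, no filter and no variance trend. Without wild type 2 the camera adjusted p was 0.148 for the iron list and 0.289 for the PAU, DAN and TIR list, and without rrp6 1 it was 0.118 and 0.468. The median of the latter was 0.35 without wild type 2, 0.25 without rrp6 1 and 1.05 with the 3 wild-type arrays as 1 group.

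The other 20 lists did not pass the camera test in rrp6, with medians from −0.57 for the alpha-specific genes to 0.42 for the exosome genes. For the exosome list the mean was −0.10, RRP6 being a member. The median of the TRAMP and Nrd1 list was 0.18, with NRD1, which binds nascent RNA in transcription termination, at 1.69 and AIR1 at 1.17. AIR1 lay 2.50 higher on wild type 3 than on wild types 1 and 2 (adjusted p = 0.0353). Adjusted over the list alone, 3 of the 8 members of that list were higher. Medians were −0.05 for cytoplasmic mRNA decay, 0.09 for mRNA 3 prime end processing, −0.02 for snoRNP proteins and 0.25 for RNA polymerases I and III. They were −0.01 for the GTP and pyrimidine synthesis genes with upstream start sites, −0.35 for histones, −0.21 for the a-specific genes, −0.04 for pheromone response and −0.05 for heat shock chaperones. They were −0.05 for the proteasome, −0.09 for meiosis, 0.38 for subtelomeric COS and YRF1 genes, −0.26 for oxidative phosphorylation and −0.02 for glycolysis. They were −0.24 for glucose-repressed genes, −0.14 for purine and pyrimidine synthesis and −0.04 for the DNA damage response. Median, mean and test differed in sign for 5 lists, those of the exosome, cytoplasmic decay, snoRNP proteins, heat shock and meiosis, none of which passed.

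Probe sets that the reference pairs with no gene were called higher more often than those with 1 gene, 5 of 1482 (0.337%) against 6 of 6094 (0.0985%; Fisher exact p = 0.0462, two-sided). Without a variance trend that difference no longer passed, at 0.188 percentage points against 0.239. Over the other settings with calls it ran from 0.358 to 7.71. At least 2-fold higher were 9.99% of the first and 4.64% of the second (Fisher exact p = 1.1e-13), a limit chosen for this class after the values were seen. Of 58 probe sets of snoRNA genes, 55 were at least 2-fold higher, against 3 of 87 of tRNA genes.

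The 15 calls rest on a spread with 2 residual degrees of freedom, and 0 remained when wild type 1, wild type 2, rrp6 1 or rrp6 2 was left out, against 300 without wild type 3. Wild type 3 is not an array of this contrast. Without it, probe sets with no spread numbered 0, against 124, and the prior degrees of freedom were 3.66, against 1.54. In the reported setting there were 365 calls at an adjusted p under 0.1, 215 higher and 150 lower. Testing only probe sets above the floor on all 6 arrays gave 316, of which 7 were among the 15. The share of calls that were higher depended on the scaling, with 147 higher and 240 lower at a common median and 84 and 16 at a common 75th percentile, against 11 and 4. The median of all probe sets was −0.05, and it moved to 0.12 with the values as deposited and to −0.19 at a common median.

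The second comparison asked what differed between the double mutant and its control, wild type 3, with 1 array each. The lone arrays are assumed to vary like the pairs of the other array set. Where values or counts below set the double mutant against wild types 1 and 2, they cross the 2 kinds of deposited values. Wild type 3 itself also differed from those 2 arrays, as given below. The labels give the double mutant the other mating type than wild type 3, so genotype and mating type differ together. MF(ALPHA)1 (7927_at), the alpha-factor pheromone gene, fell by 6.81 ± 0.16 (SE, log2; adjusted p = 0.047) and was the only probe set called. It was lower than on each of the 3 wild-type arrays. The alpha-specific list fell, with a median of −5.78 and 4 of 4 members negative (camera adjusted p = 1.9e-06; adjusted p = 0.489 with an estimated correlation). All 4 were lower when adjusted over the list alone, STE3, the receptor for a-factor, at −4.75, MF(ALPHA)2 at −7.12 as a bound, and SAG1 at −3.24. The a-specific list rose, with a median of 3.21 and 4 of 4 positive (camera adjusted p = 5.2e-08; adjusted p = 0.269 with an estimated correlation), all 4 when adjusted over the list alone. MFA2, an a-factor gene, stood at 5.87, BAR1, the protease that degrades alpha-factor, at 3.33 and STE6, the exporter of a-factor, at 3.10. The probe sets of MFA1 stood at 5.47, as a bound, and 2.10.

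snoRNA and snRNA genes rose in the double mutant as well, with a median of 2.64 and 57 of 59 positive (camera adjusted p = 8.4e-34; adjusted p = 0.507 with an estimated correlation). Of these, 44 were higher when adjusted over the list alone and 0 over all probe sets. SNR45 stood at 5.52 and SNR37 at 5.43, while SNR53 stood at −0.46 and SNR76 at −0.53, the last named after its value was seen. Among rRNA probe sets, RDN18-1 (3767_s_at) stood at 6.90 as a bound (adjusted p = 0.0914), RDN37-1 (3764_s_at) at 6.73 and RDN25-1 (3766_s_at) at 4.81.

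**Figure D2:**
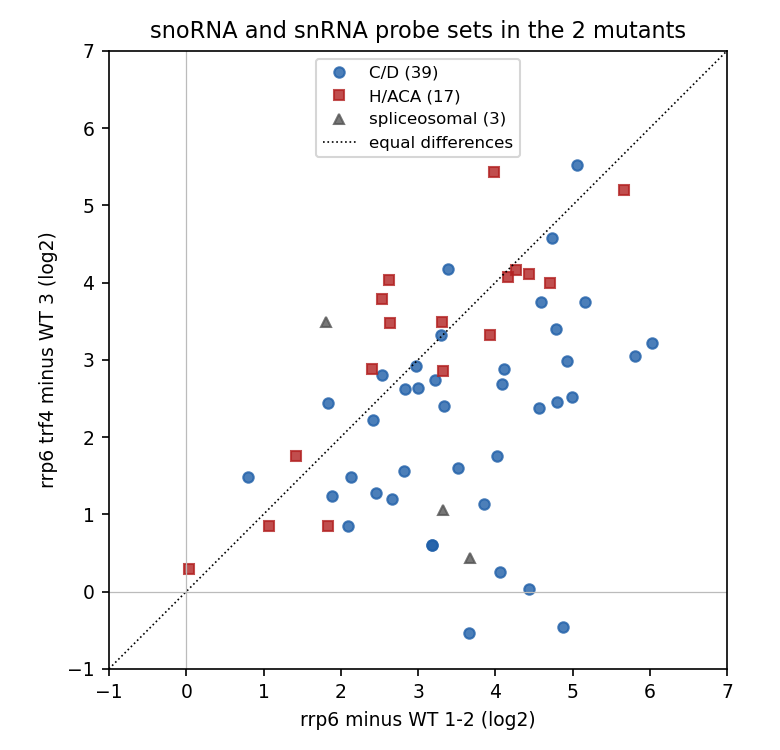
Log2 difference of each of 59 snoRNA and snRNA probe sets in rrp6 against wild types 1 and 2 (horizontal axis) and in the double mutant against wild type 3 (vertical axis). Colours mark 39 C/D, 17 H/ACA and 3 spliceosomal RNAs, and the dotted line marks equal differences. All 59 lie above 0 in rrp6 and 57 in the double mutant.

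The phosphate regulon fell in the double mutant, with a median of −1.65 and 13 of 14 negative (camera adjusted p = 6.4e-10; adjusted p = 0.269 with an estimated correlation), 10 when adjusted over the list alone. PHO84, the high-affinity phosphate transporter, stood at −5.57, SPL2 at −4.93 as a bound and PHO5 at −4.83. Amino acid synthesis genes fell, with a median of −0.52 and 37 of 41 negative (camera adjusted p = 5.2e-08; adjusted p = 0.269 with an estimated correlation), 7 when adjusted over the list alone. LYS20, of lysine synthesis, stood at −1.53 and HOM3, of threonine and methionine synthesis, at −1.50. The list's median was −1.13 at a common median, −0.85 at a common 75th percentile, −0.84 with the 3 wild-type arrays as 1 group and −0.98 against wild types 1 and 2. Mitochondrial ribosomal protein genes fell, with a median of −0.29 and 49 of 54 negative (camera adjusted p = 0.0157; adjusted p = 0.489 with an estimated correlation), 0 when adjusted over the list alone. RSM23 stood at −1.17, and the call was lost with the values as deposited, at a common median and at a common 75th percentile. The list's median turned to 0.039 with the values as deposited and a floor per array set and to 0.15 at a common level of spiked controls, was −0.54 at a common median, and was −0.17 against wild types 1 and 2. Cytosolic ribosomal protein genes fell, with a median of −0.14 and 61 of 80 negative (camera adjusted p = 0.00409; adjusted p = 0.767 with an estimated correlation), 0 when adjusted over the list alone, with RPS26B at −1.06. All probe sets of protein-coding genes had a median of −0.12, so by median this list hardly fell below other genes in the reported setting. The list's median was −1.15 at a common median, −0.87 at a common 75th percentile and −0.57 with the values as deposited. Ribosome biogenesis genes fell, with a median of −0.37 and 63 of 75 negative (camera adjusted p = 0.00819; adjusted p = 0.921 with an estimated correlation), 0 when adjusted over the list alone. ROK1, an RNA helicase of the small subunit, stood at −0.97. This list was 1.16 higher (median) on wild type 3 than on wild types 1 and 2, and against those 2 arrays its median in the double mutant was 0.87. It was 0.53 with the 3 wild-type arrays as 1 group, −0.74 at a common median and −0.16 with the values as deposited. Against them the camera adjusted p was 0.201 for cytosolic and 0.359 for mitochondrial ribosomal protein genes.

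Heat shock chaperones rose, with a median of 0.27 and 18 of 21 positive (camera adjusted p = 8.8e-04; adjusted p = 0.404 with an estimated correlation), and 1, the small heat shock protein HSP26 at 3.01, when adjusted over the list alone. At a common median the list's median was −0.26, and the call was also lost with the values as deposited, at a common 75th percentile and with the 3 wild-type arrays as 1 group, where the medians of the last 2 were 0.021 and −0.013. Proteasome genes rose, with a median of 0.17 and 29 of 34 positive (camera adjusted p = 3.8e-04; adjusted p = 0.630 with an estimated correlation), 0 when adjusted over the list alone. RPN4, their transcription factor, stood at 1.20, and the call was lost at a common median and at a common 75th percentile, where the list's median turned to −0.31 and −0.031, while it was 0.27 with the values as deposited. The PAU, DAN and TIR genes rose, with a median of 0.95 and 12 of 15 positive (camera adjusted p = 0.0045; adjusted p = 0.790 with an estimated correlation). Adjusted over the list alone, 2 were higher and 1 lower, and TIR1 stood at −2.12 and PAU10 at 1.47. The call was lost with the values as deposited and with no filter, and the median was −0.029 with the 3 wild-type arrays as 1 group. Against wild types 1 and 2 that list's median was −0.33, that of heat shock chaperones −0.043 and that of the proteasome 0.073. Subtelomeric COS and YRF1 genes rose, with a median of 0.45 and 6 of 7 positive (camera adjusted p = 0.0262; adjusted p = 0.630 with an estimated correlation), 0 when adjusted over the list alone. COS4 stood at 1.04, and the call was lost against wild types 1 and 2 (camera adjusted p = 0.566), at a common median and at a common 75th percentile. The list's median was 0.16 at a common median, 0.75 with the values as deposited, 0.72 with the 3 wild-type arrays as 1 group and 0.68 with genes in place of probe sets. The other 17 lists did not pass, the general stress list among them at a median of −0.13, with GRE1 at 3.50, HSP12 at 2.95 and GSY1 at −2.34. Against wild types 1 and 2 HSP12 stood at 0.29, HSP26 at 1.49, RPN4 at 0.57, PAU10 at 0.59, COS4 at 0.68, ROK1 at −0.34, GSY1 at −3.87 and TIR1 at −3.46. Likewise, SNR53 stood at 0.21, SNR76 at 0.14 and RDN25-1 (3766_s_at) at 8.54, the last close to a bound. Median, mean and test differed in sign for 5 lists, those of TRAMP and Nrd1, mRNA 3 prime end processing, meiosis, glycolysis and DNA damage, none of which passed.

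In the double mutant 609 probe sets were at least 2-fold higher and 348 at least 2-fold lower than in wild type 3, with 1 array each. As background, 284 probe sets were at least 2-fold apart between wild types 1 and 2, and 401 between the rrp6 replicates. The 2 comparisons share no array, and their differences correlated across probe sets (Pearson r = 0.530, Spearman rho = 0.371), although genes are not independent replicates. The planned overlap was that of called probe sets, of which 0 were shared in either direction. A 2-fold limit was not planned for it. Of the probe sets at least 2-fold higher, 222 were shared, against 34.2 from independent choice (Fisher exact p = 2.0e-139). Of those at least 2-fold lower, 76 were shared, against 13.3 (Fisher exact p = 2.8e-38). Probe sets with no gene were at least 2-fold higher more often than those with 1 gene, 13.3% against 6.37% (Fisher exact p = 4.1e-17). At an adjusted p under 0.1, 130 were called, 74 higher and 56 lower. A common median gave 124 higher and 324 lower calls, the values as deposited 23 and 7, and a common 75th percentile 21 and 6. Without a variance trend, or without any 1 of wild type 1, wild type 2, rrp6 1 and rrp6 2, 0 remained, and against wild types 1 and 2 there were 1640.

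The third comparison tested the difference between the mutants, each against its own control. No trf4 single mutant was among the samples. The contrast also crosses the 2 kinds of deposited values, and the labels change the mating type in the double-mutant set only. A difference between the mutants can therefore not be assigned to loss of TRF4. Mating-type genes, the phosphate regulon and snoRNA genes differed between the mutants as groups. The a-specific list was higher in the double mutant, with a median of 3.36 and 4 of 4 positive (camera adjusted p = 4.2e-08; adjusted p = 0.574 with an estimated correlation). With the values as deposited that median was 1.53. The alpha-specific list was lower, with a median of −4.91 and 4 of 4 negative (camera adjusted p = 6.2e-07; adjusted p = 0.574 with an estimated correlation). For both lists all 4 passed when adjusted over the list alone. The phosphate regulon was lower, with a median of −0.74 and 12 of 14 negative (camera adjusted p = 2.7e-04; adjusted p = 0.574 with an estimated correlation), 2 when adjusted over the list alone, with PHO84 at −5.02. snoRNA and snRNA genes were lower, with a median of −0.65 and 44 of 59 negative (camera adjusted p = 3.2e-06; adjusted p = 0.696 with an estimated correlation), 3 when adjusted over the list alone. The snoRNA median was −1.06 with the values as deposited, −1.03 with the 3 wild-type arrays as 1 group, −1.02 without wild type 3, −0.42 without wild type 1 and −0.39 with the values as deposited and a floor per array set. SNR53, at or near the floor on wild types 1 and 2, stood at −5.34. As values, MFA2 stood at 6.42, MF(ALPHA)1 at −6.53 and AFB1 at −4.71. RDN18-1, RDN37-1, MFA1 and MF(ALPHA)2 also fell under the rule for named genes, but these rest on arrays at the floor, so the size and order of their differences are not determined.

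Proteasome genes were higher, with a median of 0.39 and 25 of 34 positive (camera adjusted p = 8.7e-04; adjusted p = 0.696 with an estimated correlation). Mitochondrial ribosomal protein genes were higher, with a median of 0.21 and 36 of 54 positive (camera adjusted p = 0.0499; adjusted p = 0.637 with an estimated correlation). For both, 0 passed when adjusted over the list alone, and the first call was lost without wild type 3 (median 0.18, camera adjusted p = 0.442) and the second without wild type 1, wild type 2, rrp6 1 or rrp6 2 (camera adjusted p of 0.0592, 0.134, 0.0778 and 0.1003). The proteasome median was 0.25 without rrp6 1 and 0.18 with the 3 wild-type arrays as 1 group. That of the mitochondrial ribosomal proteins was 0.35 without wild type 3 or with the 3 wild-type arrays as 1 group, and 0.43 with the values as deposited under either floor. A further 5 lists passed and turned sign without wild type 3, where the double mutant was set against wild types 1 and 2. Ribosome biogenesis had a median of −0.66 (camera adjusted p = 4.2e-08), RNA polymerases I and III −0.45 (camera adjusted p = 0.0446) and the exosome genes −0.44 (camera adjusted p = 0.0177). General stress genes had 0.34 (camera adjusted p = 0.00114) and heat shock chaperones 0.35 (camera adjusted p = 0.00186). With an estimated correlation these gave adjusted p = 0.696 for ribosome biogenesis, the polymerases and general stress and adjusted p = 0.574 for the exosome and heat shock lists. The calls of the exosome, polymerase and general stress lists were also lost without wild type 1 (camera adjusted p of 0.0597, 0.251 and 0.0639) and without rrp6 2 (0.1003, 0.160 and 0.1003). Without wild type 1 the medians were −0.39 for ribosome biogenesis and 0.086 for general stress, which was 0.54 without wild type 2 and 0.68 with the values as deposited. That of heat shock was 0.16 at a common median and 0.22 at a common 75th percentile. In each of the 5 lists 0 members passed when adjusted over the list alone. Over all probe sets limma called 0, with 938 at an unadjusted p under 0.05 and a smallest adjusted p of 0.112. Without wild type 3 there were 753. No list of any comparison passed with an estimated correlation, where camera tests on 2 residual degrees of freedom. The amino acid list had an estimated correlation of 0.0091, under the preset 0.01. Its camera adjusted p in rrp6 still went from 4.5e-13 to 0.281. A larger correlation therefore does not account for that loss, and the repeat excludes no list.

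The 9 probe sets of labelled control RNAs added before hybridization lay lower against the array's median in the mutants. The mean difference (log2) was −0.69 in rrp6 and −0.69 in the double mutant, each against its own control. Scaling to these spiked controls, an alternative chosen after seeing the data, moved the median of all probe sets to 0.44 in rrp6 and 0.36 in the double mutant. It gave 524 higher and 28 lower calls in rrp6, all 15 reported ones among them, and 208 higher and 22 lower in the double mutant. In rrp6 the medians were then −0.035 for mitochondrial and −0.021 for cytosolic ribosomal proteins, −0.16 for general stress, −0.32 for amino acid synthesis and −0.57 for the phosphate regulon, and these lists still passed camera, which compares a list with the other genes. Falls of lists are therefore relative to the other genes. Ribosome biogenesis had 0.83, and the calls of the iron list (0.79) and of the PAU, DAN and TIR list (1.09) were lost. In the double mutant the mitochondrial ribosomal median turned to 0.15 and its call was lost, as were those of heat shock (0.43), PAU, DAN and TIR (1.53) and COS and YRF1 genes (0.85). Ribosome biogenesis had −0.053, cytosolic ribosomal proteins −0.46 and the proteasome 0.38. For the difference between the mutants, the calls of mitochondrial ribosomal proteins (0.17) and heat shock (0.15) were lost, and the phosphate regulon had −1.13.

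The controls were compared with each other as background. Wild type 3 is a single array, and its variation is assumed to equal that of the pairs of the other array set, so limma's calls here describe that array. At 746 called probe sets it lay apart from wild types 1 and 2, 392 higher and 354 lower, a comparison that also crosses the 2 kinds of deposited values. The same limit holds for each adjusted p given for wild type 3. Ribosome biogenesis genes were higher on wild type 3, with a median of 1.16 and 72 of 75 positive (camera adjusted p = 3.4e-14; adjusted p = 0.572 with an estimated correlation), 39 when adjusted over the list alone. Glucose-repressed genes were lower, with a median of −0.95 and 17 of 21 negative (camera adjusted p = 1.6e-04; adjusted p = 0.572 with an estimated correlation), 8 when adjusted over the list alone. Among general stress genes 20 of 38 were lower when adjusted over the list alone, with HSP12 at −2.65 and GPH1 at −2.44.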

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

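All tests in this part were chosen after the result was seen. Control probe sets for rRNA, which took no part in the comparisons, read high on mutant arrays. A value was picked out where it was more than 10 times that of every wild-type array of its set and above its own array's median (371.7 and 377.9 for the rrp6 arrays, 34.9 for the double mutant).

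On rrp6 1 the control probe set 25S e had a deposited intensity of 21423.2, and on rrp6 2 it had 19092.8, against 86.8 and 130.2 on wild types 1 and 2. Also on rrp6 2, 18S a had 595.2 and 25S d had 729.9. On the double mutant 18S a to e had 1218.7, 737.7, 738.1, 656.4 and 1034, 25S d had 1555.6 and 25S e had 2207.8, against 85.9 for 25S e on wild type 3.

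Whole rRNA carried into the labelled RNA of rrp6 1, rrp6 2 or the double mutant would raise all 10 rRNA control probe sets. The probe sets not picked out were therefore each compared with their own wild-type arrays. On rrp6 2 all 7 of them lay above both wild types, as did 45.7% of all probe sets on that array. Independent draws at that share would all lie above with a probability of 0.00415, but probe sets of the same RNA are not independent. Carried rRNA may have contributed on rrp6 2. On rrp6 1 the count was 6 of 9, against 44.3% of all probe sets, so not all were raised there. Those not above were 18S b, 18S e and 25S a, at 31.8, 13.1 and −44.4, against an array median of 371.7. Signals that low on 1 array do not settle the question. On the double mutant it was 3 of 3, against 67.2%. Independent draws at that share would all lie above with a probability of 0.304, so the test could not pass. Carried rRNA therefore stays open on both. The deletions themselves, an effect of processing on the double-mutant array set, and poly(A) tails on rRNA fragments were not tested.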

How the results depend on the processing

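The alternatives with a floor per array set and at a common level of spiked controls were chosen after seeing the data. Counts of calls depended on the setting; the values follow for rrp6, the double mutant and the difference between mutants. Values as deposited gave 401, 30 and 1, a common median 387, 448 and 0, and a common 75th percentile 100, 27 and 0. A floor at the 10th percentile gave 73, 10 and 0, an offset in place of a floor 249, 106 and 9, no filter 30, 454 and 378, and only probe sets above the floor on all 6 arrays 316, 129 and 8. Without a variance trend the counts were 11, 0 and 0, at an adjusted p under 0.1 they were 365, 130 and 0, and under 0.01 they were 0, 0 and 0. With WT 1-3 as 1 group they were 100, 66 and 8, and with genes in place of probe sets 75, 9 and 1. Values as deposited with a floor per array set gave 162, 40 and 0, and quantile normalization within each set 18, 2 and 0. A common level of spiked controls gave 552, 230 and 0. Probe sets with no spread numbered 124 in the reported setting, 1383 with no filter and 0 above the floor on all 6 arrays, where the prior degrees of freedom were 1.54, 0.857 and 5.36. Without WT replicate 3 they numbered 0, with 3.66 prior degrees of freedom. Beyond that the cause was not tested. All 15 rrp6 calls were kept with the values as deposited, at a common median, at a common 75th percentile, at a common level of spiked controls and without WT replicate 3, and 7 above the floor on all 6 arrays, where those at the floor are not tested.

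Leaving out 1 replicate at a time gave 0 to 300 calls in rrp6, 0 to 1640 in the double mutant and 0 to 753 for the difference. The 0 arose without WT replicate 1 or 2 or rrp6 replicate 1 or 2, with 1 residual degree of freedom and the lone array assumed to vary like the rest, and the highest count without WT replicate 3. Limma then gave 974 to 1245 rrp6 probe sets at an unadjusted p under 0.05.

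A replicate block (paired by number, although the labels share only a number) gave 0, 0 and 0 calls with 1 residual degree of freedom, where 2416, 1953 and 1427 had an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.515. TRP1, VPS72 and CMI8 also separated replicate 1 from replicate 2 in the same direction in the wild type and in rrp6. A difference shared by number may therefore exist, which the reported model, without a block, leaves in the spread.

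Probe sets at least 2-fold apart in the double mutant numbered 957, then 1550 at a common median, 1673 at a common level of spiked controls, 577 with genes in place of probe sets and 931 to 2082 without 1 replicate. The correlation of both mutants was 0.530, then 0.460 as deposited, 0.390 with WT 1-3 as 1 group and 0.490 to 0.569 without 1 replicate. The class difference was 0.239 percentage points, then 0.188 without a variance trend and no longer past the threshold. It stayed past it, with larger values, under the 13 other settings that gave a value, among them 3.27 as deposited, 3.49 at a common median, 2.91 at a common 75th percentile, 1.44 with WT 1-3 as 1 group, 4.15 above the floor on all 6 arrays and 7.71 at a common level of spiked controls. Settings with 0 calls higher give no value. Lists passing in rrp6 numbered 9, then 14 at a common median and 15 at a common 75th percentile. With an estimated correlation 0 lists passed in rrp6, 0 in the double mutant (12 reported) and 0 for the difference (11 reported).

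Medians of lists turned sign, the cause not being tested. With WT 1-3 as 1 group, ribosome biogenesis had −0.10 in rrp6, 0.53 in the double mutant and 0.50 for the difference. The PAU, DAN and TIR list had −0.029 in the double mutant. For the difference, exosome genes had 0.24, RNA polymerases I and III 0.54 and general stress −0.61. Without 1 replicate at a time, the double mutant gave −0.38 to 0.87 for ribosome biogenesis and −0.33 to 0.98 for PAU, DAN and TIR. The difference gave −0.87 to 0.50 for ribosome biogenesis, −0.59 to 0.24 for exosome genes, −0.54 to 0.53 for RNA polymerases I and III, −0.61 to 0.54 for general stress and −0.0043 to 0.39 for heat shock. In each, the turned sign arose without WT replicate 3. In the double mutant heat shock had −0.26 at a common median, −0.013 with WT 1-3 as 1 group and −0.043 without WT replicate 3, and the proteasome had −0.31 at a common median and −0.031 at a common 75th percentile. Mitochondrial ribosomal proteins had 0.039 there as deposited with a floor per array set and 0.15 at a common level of spiked controls. Heat shock had −0.0045 for the difference with WT 1-3 as 1 group. Cytosolic ribosomal proteins kept a negative median, −0.71 at a common median in rrp6 and −1.15 in the double mutant, against −0.10 and −0.14.

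Across 19 other settings with the preset correlation, 4 of 9 rrp6 lists (snoRNA, mitochondrial ribosomal, phosphate, amino acid) kept direction and threshold in all. So did 5 of 12 in the double mutant (snoRNA, a-specific, alpha-specific, phosphate, amino acid) and 4 of 11 for the difference (snoRNA, a-specific, alpha-specific, phosphate). Calls were lost in 10 settings for the rrp6 PAU, DAN and TIR list, in 7 for mitochondrial ribosomal, heat shock and COS and YRF1 genes in the double mutant, and in 9 for mitochondrial ribosomal genes, 5 for exosome genes and 5 for RNA polymerases I and III in the difference. Each other list that was not kept in all lost its call in 2 to 5. Of 271 values for the 15 rrp6 calls, 178 stayed past the threshold, 93 did not and 0 turned sign. The median of all probe sets in the double mutant was −0.08, then −0.25 at a common median, 0.25 as deposited with a floor per array set and 0.36 at a common level of spiked controls. Signal near the floor limits what can be called, since a gene at the floor has only a bound.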

Other observations

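The tests on mating type and the relabelling of snoRNA classes were chosen after the results were seen, as were the genes named in the next 3 paragraphs. The tests of snoRNA level, neighbours, length and baseline and of downstream genes were written down beforehand.

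The telomerase RNA TLC1 stood at 1.25 and 1.22 (log2) at its 2 probe sets in rrp6 and at 1.24 and 1.40 in the double mutant. RPR1, the RNA of RNase P, stood at 1.71 in rrp6 and 0.49 in the double mutant, where it was −0.05 against wild types 1 and 2. None was called, with adjusted p in rrp6 of 0.0701 and 0.0889 for TLC1 and 0.0537 for RPR1. Probe sets of tRNA genes had a median of 0 in rrp6, with 3 of 87 at least 2-fold higher. As values, SNR76 stood at 3.66 in rrp6 and −0.53 in the double mutant and SNR69 at 4.06 and 0.25. Neither difference between mutants was called. Against wild types 1 and 2, SNR76 stood at 0.14 and SNR69 at 0.79 in the double mutant.

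SUL2, a sulphate permease, stood at −2.88 in rrp6 and at −3.78 on wild type 3, both against wild types 1 and 2. STR3 stood at −3.04 and −3.61, MET2 at −2.86 and −3.60, and SUL1 at −2.38 and −4.05. None of these 4 single genes was called in rrp6, with adjusted p of 0.0537, 0.0595, 0.0568 and 0.218. On wild type 3 the adjusted p was 0.0278, 0.0346, 0.0313 and 0.0799.

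TRP1 separated replicate 1 from replicate 2 in both strains, by at least 3.53 in the wild type and at least 3.16 in rrp6 (replicate 2 minus replicate 1, log2), since replicate 1 lay at the floor. At a 4-fold limit 15 probe sets passed in the wild type and 28 in rrp6. Those passing in both strains were 3 in the same direction and 1 in opposite directions, against 0.0533 in either direction if the strains were independent. The others in the same direction were VPS72 (−2.36 and −2.87) and CMI8 (−2.63 and −2.25, bounds since replicate 2 lay at the floor). Wild type 3 had the low value of TRP1 and the double mutant the high one, 5.44 and 8.02.

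The mating-type genes ran against the labels. The mean of the alpha-specific genes minus that of the a-specific genes was 5.39, 5.42, 5.38, 4.55 and 5.47 on the wild-type and rrp6 arrays, labelled Mat a, and −3.70 on the double mutant, labelled Mat alpha. An exchange of the wild type 3 and double-mutant arrays is argued against, since RRP6 and PAP2 were both lower on the double-mutant array, the smaller drop being −2.17. Expression of both mating types in the double mutant is argued against by a mean of −5.48 for its alpha-specific genes. The sign was opposite to the label on 6 of 6 arrays, which is consistent with mating types exchanged in the labels, a candidate explanation found and tested on the same data.

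C/D snoRNAs stood lower than H/ACA snoRNAs in the double mutant relative to rrp6, with classes assigned from textbook knowledge. The gap of the mean differences was −1.58 over 39 C/D and 17 H/ACA RNAs (permutation p = 0.00015), but snoRNAs are not independent replicates. Signal level is argued against as the whole cause (gap −1.55 with wild-type level in the model, permutation p = 3e-05), as is the counting of neighbours (−1.33 with neighbours within 1 kb averaged, permutation p = 0.00029). With length in the model, where C/D RNAs had a median of 96 nucleotides and H/ACA 203, the gap was −0.93 (permutation p = 0.0820), and 49.7% of the gap was present between wild type 3 and wild types 1 and 2. Length and the baseline of differently processed controls stay open, so the gap cannot be told apart from them and the class may not be its source.

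Readthrough from snoRNA genes into protein-coding genes next downstream on the same strand was a hypothesis. The median of 26 such genes minus that of 5249 others was 0.16 in rrp6 (95% bootstrap interval −0.07 to 0.43, permutation p = 0.115) and 0.0043 in the double mutant (−0.12 to 0.37, permutation p = 0.969). The bound set beforehand counted a missed p as evidence against readthrough, which was wrong because a missed p excludes nothing. The intervals leave a small shift open. YDR042C, seen before this test, lies downstream of a snoRNA gene and stood at 2.02 in rrp6 and 4.67 in the double mutant. On wild type 3 it stood at −1.58 against wild types 1 and 2. Against those 2 arrays the double mutant stood at 3.09.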
